A study of Homo sapiens with 23 samples.

How the data were processed

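The 13 samples of smokers and 10 of non-smokers were alveolar macrophages, the resident phagocytes of the air spaces, washed from the lungs by bronchoalveolar lavage. Per the labels' protocols, the cells were examined under a microscope after Wright stain to check that nearly all were macrophages, and were then frozen. Per the same protocols, a small amount of total RNA was amplified to cDNA with an isothermal kit, fragmented, labelled with biotin and hybridised to an Affymetrix exon array, with 1 array per sample. Per the submitters' processing notes, the arrays were read with GCOS and summarised with RMA, a method of background correction, normalization and summary of probes, with annotation on hg18. Their versions, the steps run and the set of probes that each value summarises are not given in the sources used here, nor whether all arrays were normalized together. The methylation measurements that the series title speaks of were not analysed here.

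The deposited values are log2 expression, 1 value per row and array, for 22011 rows and 23 arrays. Values ran from 1.002 to 13.46, and the array medians from 5.644 to 5.755. The deposited values were used without further normalization, and no filter on dim rows was applied. Depth has no meaning for arrays, and the number of arrays limits the precision. Gene symbols came from the platform's annotation table. It gave 1 symbol for 14432 rows and several for 2408, and 5171 rows had no symbol there. Of the rows with 1 symbol, 14404 matched a current gene by Entrez identifier in the RefSeq table of the GRCh38 assembly, which changed 0 symbols. No gene was named from a row with several symbols. For that reason AHRR and NQO1, chosen for naming in advance, have no value here. No coordinates were used.

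Groups came from the labels. A suffix in the description label put the arrays in 2 sets, called batches 1 and 2 here. Batch 1 held 5 non-smokers and 7 smokers, and batch 2 held 5 non-smokers and 6 smokers. The leading number of the description lay between 1 and 7 in smokers and between 8 and 12 in non-smokers in both batches, so any order it marks runs with the group. The description of 3 smoker arrays carried the letter E where the other smokers carried S, and the labels do not say what it marks. Leading numbers 2 to 12 occurred once in each batch, always in the same group and with the same letter. The number could thus mark 1 person measured in both batches. This was not checked, and all tests and splits here treat the 23 arrays as independent. The highest correlation between any 2 arrays was 0.9852, and 0 arrays were identical. The replicate numbers in the titles are shared by smokers and non-smokers but cannot name the same people in both groups, and the check of them stands in the closing section.

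Differences between smokers and non-smokers were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with batch and group in the fit of all 23 arrays. P-values were adjusted by the Benjamini-Hochberg method over all 22011 rows, and a row was called at an adjusted p under 0.05. A second count took called rows that differed by 1.5-fold or more. Positive differences mean higher values in smokers, and standard errors (SE) are limma's moderated ones. Beside it, each batch was fitted alone, the interaction of smoking and batch was tested, and the batch term was counted. No covariate other than batch was used.

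In all, 23 gene lists and 9 lists of cell type markers were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives below. The lists were tested together with limma's camera, with its preset inter-gene correlation of 0.01, over 14210 genes, each by its row of highest mean. Camera with an estimated correlation and fry, a directional test of the list's own members, were alternatives. Other alternatives were: no batch term, batch as a random block, the replicate block, median centring, quantile normalization, 2 filters on dim rows, eBayes with trend and robust settings, array weights, the 3 letter-E arrays left out, each array left out in turn, each batch alone, normal scores of ranks, counts of gene symbols, and the mean of a gene's rows. Leaving out 3 arrays of narrow spread was added after the data had been seen.

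The genes named were, by that rule, the 15 largest called rises and the 15 largest called falls among rows with 1 symbol and the same sign in both batches. To these came up to 4 members of smallest p in each list with a call or a passing test, up to 2 in other lists, and 14 genes named in advance. Members named outside this rule are marked as chosen after their values were seen. Genes on the Y chromosome, XIST, TSIX and genes whose level can show a person's genotype were left out of all tables of single genes but stayed in the fits and counts.

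The scripts were tested on simulated data with the real design and 22011 rows, of which 200 were changed. The fit recovered 56.7% of the rows changed by 0.5 log2 units, 86.6% of those changed by 1 and 100% of those changed by 2. Of its 171 calls 9 were false, and it made 0 calls in data with no change. In the list test a shifted list passed, and 0 of 9 unshifted lists did. The simulated rows varied independently of each other, so this check cannot show how correlation among real genes affects the list test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.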

Results

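Gene expression was measured in alveolar macrophages on 13 arrays of smokers and 10 of non-smokers, in 2 batches that both held both groups. Whether the batches share people was not checked. The series asks how long-term cigarette smoke exposure changes gene expression in these cells, beside DNA methylation. Values are log2 expression. The 23 arrays had medians between 5.644 and 5.755. Over the rows of an array the SD was 1.654 to 1.876 on 20 arrays and 1.36 to 1.482 on the other 3, which were non-smoker 5 and smokers 2 and 10, all of batch 1. Those 3 arrays also correlated less with the rest, with a mean r across rows of 0.817 to 0.868 against 0.937 to 0.955. Rows are not independent replicates, so these r describe the arrays only.

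**Figure D1:**
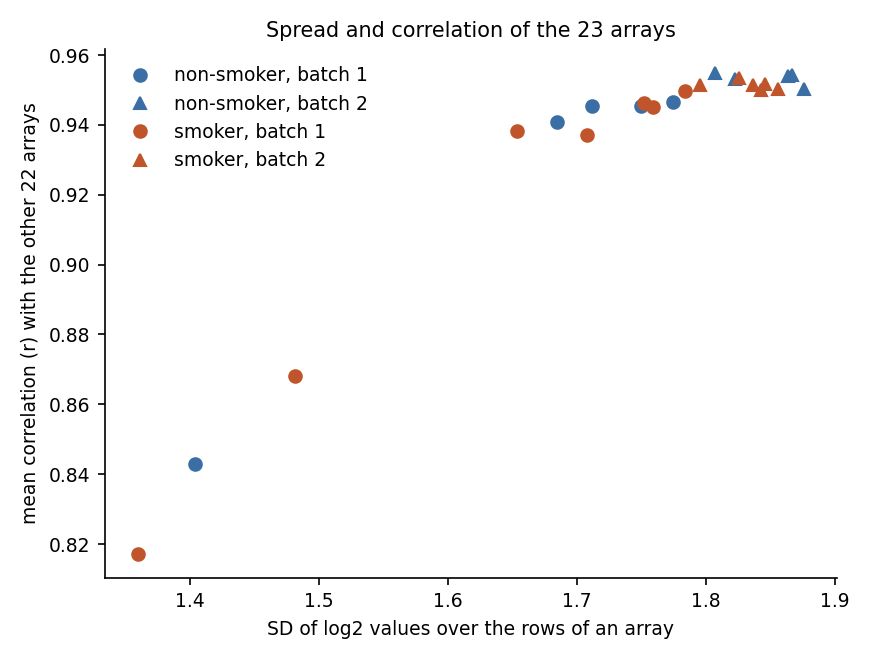
Spread and correlation of the 23 arrays: the x axis gives the SD of the log2 values over the rows of an array, the y axis its mean Pearson r with the other arrays, colours the group and shapes the batch. The 3 arrays at the lower left, with SDs of 1.36, 1.40 and 1.48, are smoker 2, non-smoker 5 and smoker 10.

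Alveolar macrophages of smokers differed most in a proton pump subunit, a cytochrome P450 and macrophage elastase. ATP6V0D2 (array row 3105749), a subunit of the vacuolar proton pump, had a log2 value of 8.26 ± 0.85 (SD, n = 13) in smokers and 5.63 ± 0.55 (SD, n = 10) in non-smokers. This is a rise of 2.65 (SE 0.29) or 6.26-fold, with a limma adjusted p of 8.94e-05. CYP1B1 (array row 2548699), an enzyme induced through the aryl hydrocarbon receptor, stood at 6.75 ± 1.06 (SD, n = 13) against 4.30 ± 0.20 (SD, n = 10), a 5.56-fold rise with an adjusted p of 1.56e-04. MMP12, macrophage elastase, stood at 6.04 ± 1.19 against 4.02 ± 0.44, a 4.09-fold rise with an adjusted p of 0.00762. Set against the non-smoker median of their own batch, all 13 smokers lay above it for ATP6V0D2 and CYP1B1, and 12 of 13 for MMP12 (6 of 7 in batch 1 and 6 of 6 in batch 2). In smokers the interferon-induced chemokine CXCL11 and the club cell secretoglobin SCGB1A1 were among the genes that fell furthest, to 3.67-fold and 3.24-fold lower levels. Of the 30 largest changes, 10 had 1 group with a mean at least 1 log2 unit under the lowest array median: CYP1B1, MMP12, S100B, FLT1, GASK1B, SLC7A11, TDRD9 and SLCO4C1 in non-smokers, and CXCL11 and PDGFD in smokers. No detection value was used, so the folds given for these genes, and their place among the largest changes, are not exact.

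Across all 22011 rows, limma called 190 at an adjusted p under 0.05, 97 higher and 93 lower in smokers. Of these, 103 differed by 1.5-fold or more (48 higher, 55 lower). The calls covered 162 gene symbols, 82 higher and 80 lower, and 20 called rows had several symbols and 8 none. All 190 differences had the same sign in both batches. Batch 2 alone gave 248 calls, which held 102 of the 190, and batch 1 alone gave 1 call, a row with several symbols. At an unadjusted p under 0.05, 162 of the 190 passed in batch 1 alone and 187 in batch 2 alone. The 190 were chosen by the fit of both batches together, so equal signs and small p in each batch follow in part from that choice. Over all rows, 868 passed in batch 1 alone and 2686 in batch 2 alone, where chance alone would give 1101. The count was 498 without the 3 arrays of narrow spread, with 188 of the 190 kept, 307 without smoker 2 alone, and 69 without the 3 letter-E smoker arrays.

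**Figure D2:**
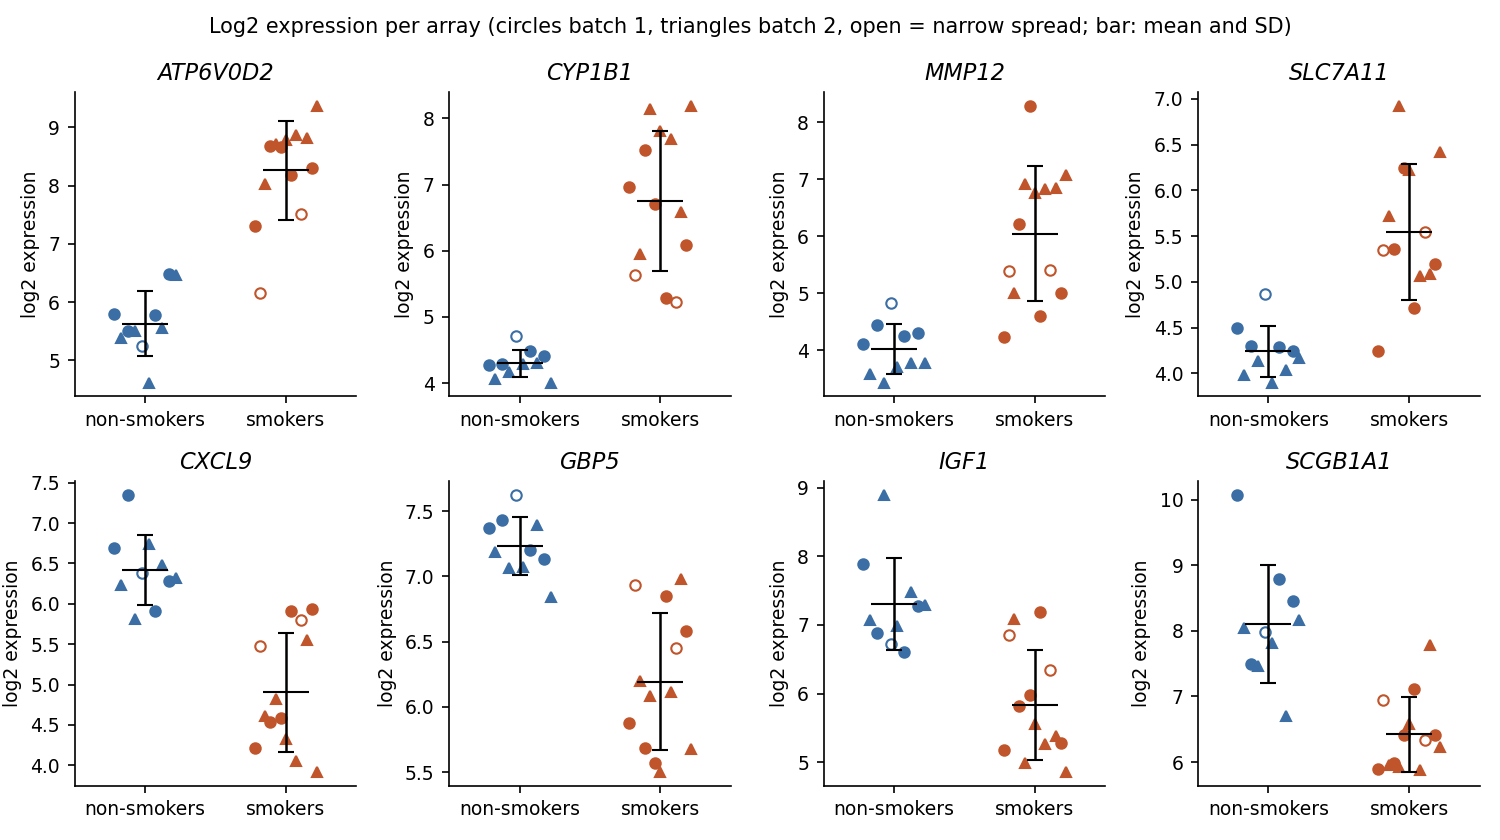
Log2 expression of 8 named genes on each array, by group: circles are batch 1, triangles batch 2, open symbols the 3 arrays of narrow spread, and black bars the mean and SD. ATP6V0D2, CYP1B1, MMP12 and SLC7A11 were higher in smokers (differences 2.65, 2.48, 2.03 and 1.31), and CXCL9, GBP5, IGF1 and SCGB1A1 were lower (differences -1.53, -1.05, -1.48 and -1.69).

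The other 12 of the 15 largest rises ranged from 1.05 to 1.98. They were S100B (1.98), the vascular endothelial growth factor receptor FLT1 (1.69), the podosome adaptor SH3PXD2B (1.46), the broad protease inhibitor A2M (1.43), GASK1B (1.33), the cystine transporter SLC7A11 (1.31), SSBP3 (1.23), TDRD9 (1.18), the organic anion transporter SLCO4C1 (1.13), PRXL2A (1.09), the lipid-presenting CD1E (1.07) and the glutathione transferase MGST1 (1.05). The 15 largest falls ranged from -1.90 to -1.21. The thiamine transporter SLC19A3 fell by 1.90 and the terminal complement component C8B by 1.82. Next to CXCL11 (-1.88) and SCGB1A1 (-1.69) came the growth factor PDGFD (-1.63), TCEA3 (-1.57), the chemokine CXCL9 (-1.53), the growth factor IGF1 (-1.48) and ITIH5 (-1.47). The transcription factors SNAI2 (-1.34) and MYB (-1.32), the granulocyte surface protein CEACAM8 (-1.29), the chemokine CCL20 (-1.29), the lysophosphatidic acid receptor LPAR3 (-1.27) and the amine oxidase AOC3 (-1.21) completed them. Adjusted p-values of these 30 genes ran up to 0.0329, for A2M.

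Of the 52 named genes that were called, 41 stayed called on leaving out each array in turn. The other 11 lost the call in at least 1 of the 23 fits: CYCS in 20, C3AR1 in 14, C8B in 12, A2M, CD3D and MMP2 in 11 each, CD207 and CEACAM8 in 8 each, CD1A in 7, INHBA in 5 and TXNRD1 in 1. Their highest adjusted p in limma ran from 0.0508 for TXNRD1 to 0.1 for CYCS, both without non-smoker 8. Leaving out any array other than non-smoker 5 or smoker 2 ended between 1 and 10 of these calls. Without the 3 letter-E arrays 27 of the 52 stayed called. The calls that ended there were those of GASK1B, PRXL2A, CD1E, SLC19A3, CXCL11, C8B, IGF1, CEACAM8, LPAR3, GCLC, TXNRD1, MMP2, CSF1, CD1C, CD1A, C3AR1, C1QA, INHBA, CYCS, PCOLCE2, CD69, CD4, IL7R, CD3D and CD207. With no batch term A2M, GCLC, TXNRD1, C3AR1, CD4 and IL7R were not called, and with quantile normalization MMP2, C1QA, INHBA, CYCS, CD3D and CD207 were not. Among the named genes without a call, 21 were called without the 3 arrays of narrow spread, 33 with array weights and 11 in batch 2 alone.

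Genes of the antioxidant response that the transcription factor NRF2 drives were higher in smokers as a list. The list passed camera (adjusted p = 1.74e-06), with adjusted p = 0.0566 with an estimated correlation. Of 23 measured members 4 rose, 0 fell and 19 did not pass; adjusted over the list alone, 9 rose and 1 fell. The 4 were SLC7A11 at 2.48-fold, MGST1 at 2.07-fold, GCLC, which makes the first enzyme of glutathione synthesis, at 1.64-fold and the thioredoxin reductase TXNRD1 at 1.5-fold. The list's median was 0.02 in batch 1, where it did not pass, and 0.32 in batch 2. Of the aryl hydrocarbon receptor list, only CYP1B1 was called among 7 measured members. CYP1A1 differed by 0.12 (SE 0.11, adjusted p = 1) and the receptor AHR itself by -0.20 (SE 0.12, adjusted p = 0.875). That list did not pass (adjusted p = 0.208), and its median was -0.01 where its mean was 0.34.

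The list of matrix proteases and their inhibitors passed camera as higher (adjusted p = 5.21e-04). It did not pass with an estimated correlation (adjusted p = 0.331) or with fry (adjusted p = 0.158). Its median was -0.00 in batch 1, where it did not pass, and 0.17 in batch 2. Of 30 members 3 rose and 0 fell; adjusted over the list alone, 6 rose and 1 fell. The 3 were MMP12, the gelatinase MMP2 (1.47-fold) and A2M (2.70-fold), of which A2M inhibits proteases. SPP1, osteopontin, was 2.32-fold higher without passing (adjusted p = 0.121); it differed by 0.35 in batch 1 (adjusted p = 1) and by 2.14 in batch 2 (adjusted p = 0.038), with an interaction adjusted p of 1. The lysosome and vacuolar ATPase list passed as higher (adjusted p = 0.0126), with adjusted p = 0.443 with an estimated correlation, and ATP6V0D2 was the 1 called member of 34. Its other examples were ATP6V1A (0.29, adjusted p = 0.1), LAMP1 (0.42, adjusted p = 0.102) and LIPA (0.71, adjusted p = 0.406). Adjusted over the list alone 3 rose, and without the 3 arrays of narrow spread 4 did, among them ATP6V1A (adjusted p = 0.00655) and LIPA (adjusted p = 0.0012). Without single arrays this list did not pass: adjusted p was 0.096 without non-smoker 5, 0.0522 without non-smoker 6, 0.0509 without non-smoker 8 and 0.0638 without smoker 1.

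Cholesterol synthesis genes and heat shock and unfolded protein response genes each passed camera as higher with 0 members called by limma, of 20 and 31, and with 4 and 9 at an unadjusted p under 0.05. Their adjusted p-values were 0.00838 and 0.00751, and these became adjusted p = 0.436 and adjusted p = 0.106 with an estimated correlation. Without non-smoker 5 both lists had an adjusted p of 0.111. The first list also holds fatty acid enzymes, and its 4 were IDI1 and the fatty acid desaturases FADS1, FADS2 and SCD. FADS1 differed by 0.38 (adjusted p = 0.154) and SCD, against the direction of the list, by -0.57 (adjusted p = 0.19). Without the 3 arrays of narrow spread both were called with the same signs (adjusted p = 0.0332 and adjusted p = 0.00292). Adjusted over that list alone, 1 rose and 1 fell in it. In the second, DNAJB9 differed by 0.28 (adjusted p = 0.1) and ASNS by 0.38 (adjusted p = 0.132), and adjusted over the list alone 4 rose and 1 fell. Without the 3 arrays of narrow spread, BAG3 was the 1 member of the second list called, as higher (adjusted p = 0.0451).

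Interferon response genes were lower in smokers as a list, with 1 of 37 measured members above 0 and a median difference of -0.38 (-0.31 in batch 1 and -0.34 in batch 2). The list passed camera (adjusted p = 3.03e-18) and also passed with an estimated correlation (adjusted p = 0.0317). Of the 37, 5 fell and 0 rose; adjusted over the list alone, 17 fell and 1 rose. The largest falls were the chemokines CXCL11, at 3.67-fold lower, and CXCL9, at 2.89-fold lower. The guanylate-binding proteins GBP5 and GBP4 were 2.07-fold and 1.60-fold lower. In the plot of single genes, CXCL9 and GBP5 of all 13 smokers lay below the non-smoker median of their own batch.

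Complement genes were lower as a list (camera adjusted p = 5.54e-06, adjusted p = 0.0317 with an estimated correlation). Its median was -0.13 in batch 1 and -0.19 in batch 2. Of 20 members 3 fell and 0 rose, and adjusted over the list alone 7 fell. Factor B (CFB) fell by 0.46, the recognition subunit C1QA by 0.45 and the anaphylatoxin receptor C3AR1 by 0.70. C3 itself differed by -0.36 (adjusted p = 0.121). The list of resident alveolar macrophage genes passed as lower (adjusted p = 0.00223), with adjusted p = 0.331 with an estimated correlation. It shares 15 of its 25 measured members with other lists. In it 3 genes fell, C1QA, the collagen-binding PCOLCE2 (-0.55) and the activin subunit INHBA (-0.60). The integrin ITGAX, or CD11c, rose by 0.94. Adjusted over the list alone, 5 fell and 3 rose. With all arrays PPARG differed by -0.26 (SE 0.16, adjusted p = 0.867) and FABP4 by -0.34 (SE 0.16, adjusted p = 0.643). PPARG was called as lower in batch 2 alone (adjusted p = 0.0269; interaction adjusted p = 1), and FABP4 without the 3 arrays of narrow spread (adjusted p = 0.0377) and with array weights (adjusted p = 0.0209). The scavenger receptor CD163 differed by 0.08 (SE 0.16, adjusted p = 1).

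Markers of cells other than macrophages also moved with the group. The list of T and NK cell markers was lower in smokers, with 1 of 28 members above 0 and a median of -0.16 (-0.21 in batch 1 and -0.19 in batch 2). It passed camera (adjusted p = 2.36e-09), also with an estimated correlation (adjusted p = 0.0317). In it CD69 fell by 0.85, the interleukin-7 receptor IL7R by 0.89, CD3D by 0.71 and CD4, which macrophages express too, by 0.42; adjusted over the list alone, 8 fell. None of these 4 calls held without the 3 letter-E arrays, where the list still passed, and those of CD4 and IL7R also ended with no batch term. Airway epithelium markers passed as lower (adjusted p = 0.0169), with adjusted p = 0.395 with an estimated correlation, and SCGB1A1 was the 1 called member of 24. SCGB1A1 differed by -2.11 in batch 1 and -1.25 in batch 2. Without non-smoker 5 that list had an adjusted p of 0.096, and without smoker 9 one of 0.0537. Dendritic cell markers passed as higher (adjusted p = 0.0328), with adjusted p = 0.443 with an estimated correlation and 0.091 without the 3 arrays of narrow spread. Only CD1E (2.10-fold), CD1C (1.91-fold), CD1A (1.65-fold) and the langerin gene CD207 (1.62-fold) rose among its 18 members, whose median was 0.00. Without single arrays its adjusted p was 0.072 (non-smoker 2), 0.0812 (non-smoker 9), 0.138 (non-smoker 10), 0.106 (smoker 2), 0.0544 (smoker 4) and 0.0912 (smoker 7). Granulocyte CEACAM8 was 2.45-fold lower, but the neutrophil list did not pass in the main fit (adjusted p = 0.208). That list passed with the replicate block and without rows below the median.

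**Figure D3:**
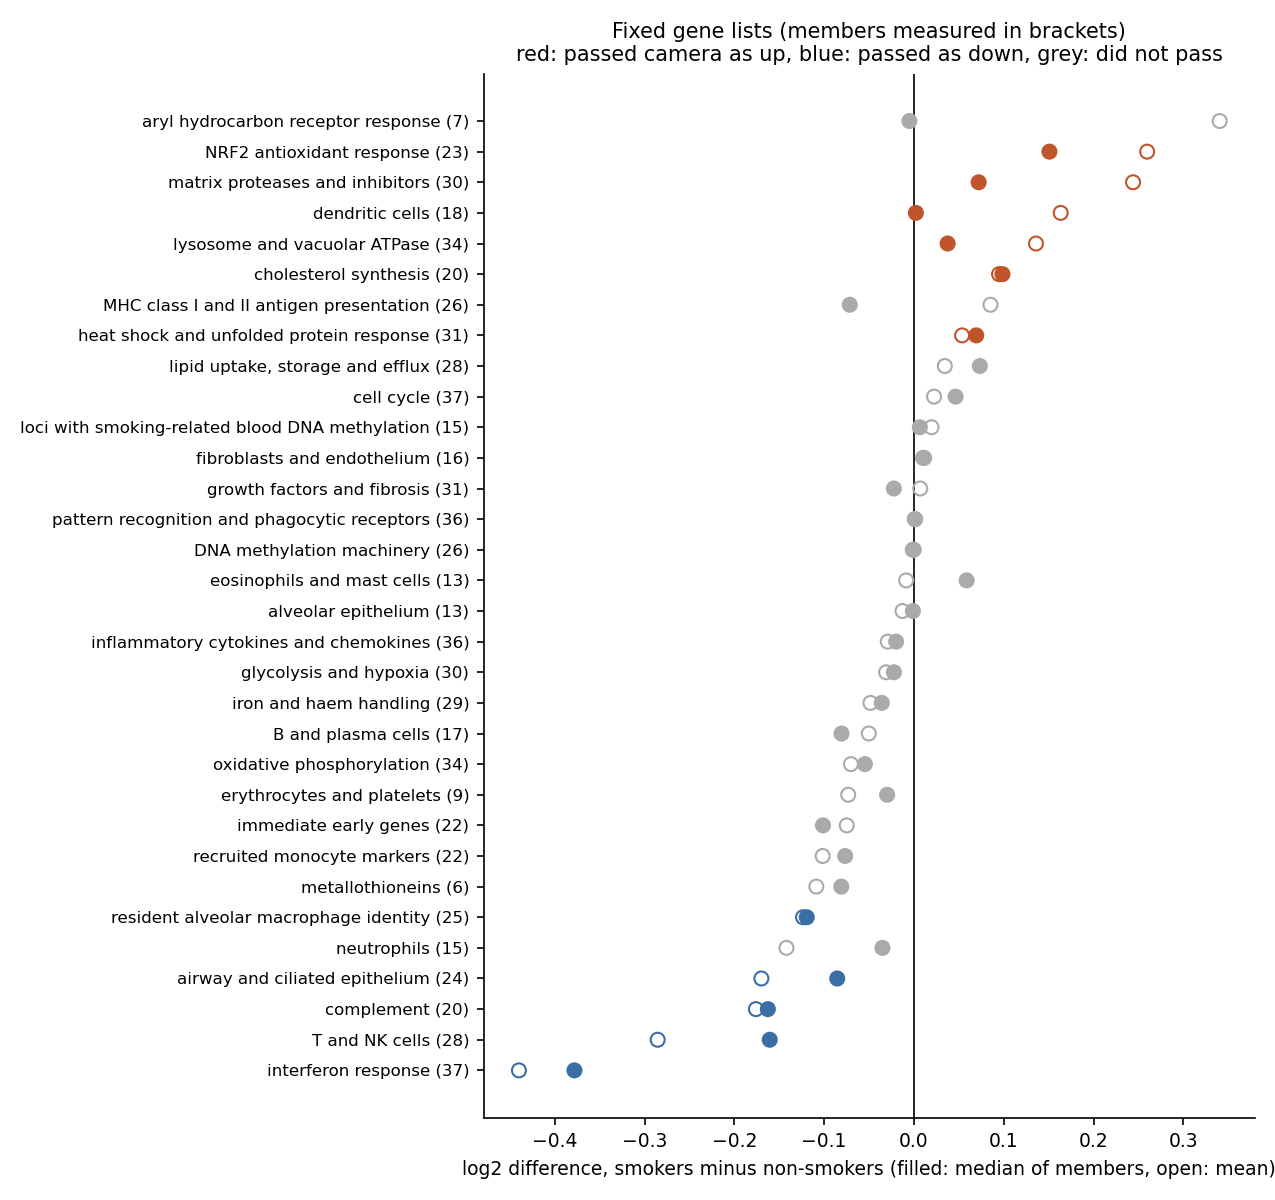
Log2 differences of the 32 fixed lists, smokers minus non-smokers: filled points are the median and open points the mean over the measured members, whose number stands in brackets. Red lists passed camera as higher, blue ones as lower and grey ones did not pass. The interferon list lies furthest below 0, with a median of -0.38.

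In the growth factor list (adjusted p = 0.873), FLT1 rose 3.22-fold and NRP1, its co-receptor, 1.36-fold, and IGF1 and INHBA were 2.80-fold and 1.52-fold lower; adjusted over the list alone, 3 rose and 2 fell. In the cytokine list (adjusted p = 0.43), the macrophage growth factor CSF1 rose 1.56-fold and CCL20 was 2.44-fold lower; adjusted over the list alone 4 rose and 3 fell, and without the 3 arrays of narrow spread 2 and 3. In the MHC list (adjusted p = 0.98), CD1A, CD1C and CD1E were the 3 called of 26 members, and CD80 differed by -0.42 (adjusted p = 0.0715). In it 4 rose and 1 fell adjusted over the list alone, as many as were called without the 3 arrays of narrow spread. In the list of pattern recognition receptors (adjusted p = 0.946), ITGAX rose and C3AR1 fell among 36 members. Members that passed adjusted over the list alone were 4 that rose and 5 that fell, and without the 3 arrays of narrow spread 3 rose and 5 fell. Iron and haem genes (adjusted p = 0.225) held the fall of ACO1 (-0.56), an iron regulatory protein; adjusted over the list alone 1 rose and 2 fell, and without the 3 arrays of narrow spread 2 fell. Lipid uptake and efflux genes (adjusted p = 0.82) held 0 limma calls among 28 members (13 at an unadjusted p under 0.05). Adjusted over the list alone 5 rose and 4 fell, and without the 3 arrays of narrow spread 3 rose and 4 fell. With all arrays TREM2 differed by 0.45 (adjusted p = 0.077) and ABCG1 by -0.33 (adjusted p = 0.154).

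Because the series concerns methylation, enzymes of DNA methylation and loci known to differ in methylation in smokers' blood were examined too. Of the 26 measured genes of the methylation machinery limma called 0, with 2 at an unadjusted p under 0.05 (list adjusted p = 0.969). Adjusted over the list alone 1 rose and 1 fell, the serine hydroxymethyltransferases SHMT2 (0.27, adjusted p = 0.153 over all rows) and SHMT1 (-0.28, adjusted p = 0.157). Without the 3 arrays of narrow spread 1 member rose and 1 fell, SHMT2 (adjusted p = 0.0474) and GADD45B (adjusted p = 0.0281), the latter named after its values were seen. DNMT1 differed by 0.12 (SE 0.07, adjusted p = 0.764). Of the 15 blood loci limma called 0 too, with 1 at an unadjusted p under 0.05 (list adjusted p = 0.946). F2RL3 differed by -0.06 (SE 0.08, adjusted p = 1) and GPR15 by -0.08 (SE 0.18, adjusted p = 1).

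In all, 11 of 32 lists passed camera, 6 as higher and 5 as lower. Other splits of the arrays within batches, described in the closing section, passed a median of 3 lists, so a pass in camera alone is weak evidence. With an estimated correlation 3 passed, the interferon, complement and T and NK cell lists, and fry passed 4, those 3 and the NRF2 list. Without non-smoker 5 camera passed 7, and in batch 1 alone 6, of which 4 were among the 11. Without the 3 letter-E arrays the cholesterol and lysosome lists did not pass. Median and mean differed in sign for the aryl hydrocarbon receptor, MHC, growth factor and eosinophil and mast cell lists. The MHC test pointed down with its median of -0.07, against a mean of 0.09. The tests of the DNA methylation and alveolar epithelium lists pointed up and that of the pattern recognition list down, each against the sign of its own median and mean, which rounded to -0.00 and -0.00, -0.00 and -0.01, and 0.00 and 0.00.

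The batches differed strongly: 6340 rows were called for the batch term, 2389 higher and 3951 lower in batch 2. The smoking effect was tested for a difference between batches by the interaction term, and limma called 0 rows, with 818 at an unadjusted p under 0.05 where chance alone would give 1101. Of the 190 calls, 138 had a larger difference in size in batch 2. For example, CYP1B1 differed by 1.77 in batch 1 and 3.23 in batch 2 (interaction adjusted p = 1), and MMP12 by 1.21 and 2.91 (interaction adjusted p = 1).

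**Figure D4:**
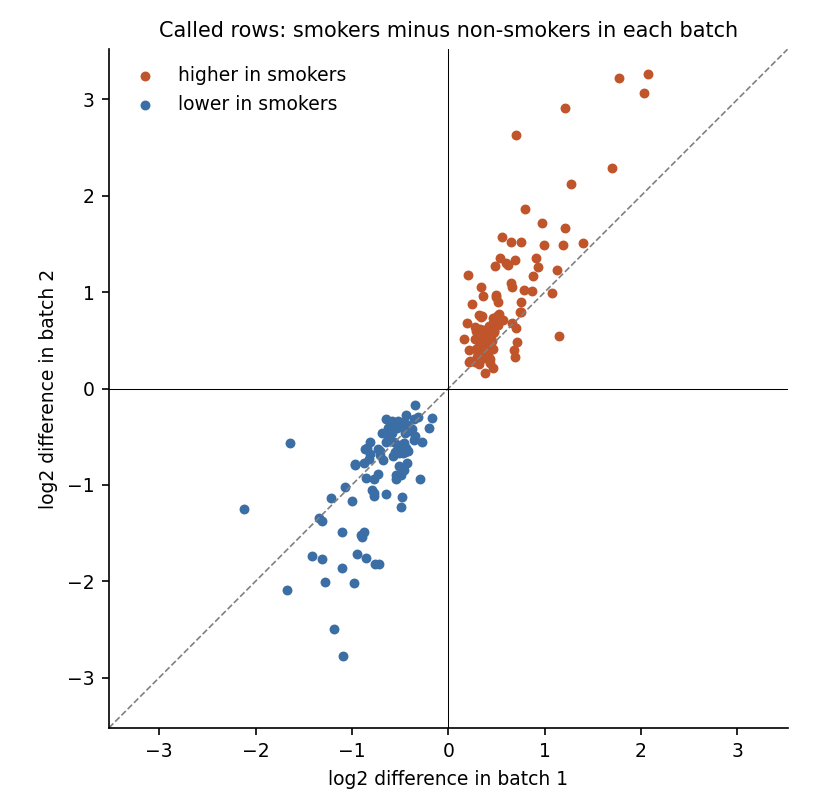
Log2 differences, smokers minus non-smokers, of the 190 called rows in batch 1 (x axis) and batch 2 (y axis): red rows are higher and blue rows lower in smokers, and the dashed line marks equal differences. All 190 have the same sign in both batches, and 138 lie further from 0 in batch 2. The rows were chosen by the fit of both batches together, which favours equal signs.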

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

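The count of other splits for calls of 1.5-fold or more was a test chosen after its result was seen, tests without the 3 arrays of narrow spread were added after the data had been seen, and of the 3 tests on the batch ratio, the one without the letter-E arrays alone was chosen, and the reading of the others changed, after their values were seen.

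Among the 10 non-smokers, 1 array stood apart from the rest in 19 of 121 measures, of which 118 were named genes; chance would give about 5.9 among the genes. The check was set up for groups of up to 10 arrays, so the 13 smokers, among them smokers 2 and 10 of narrow spread, were not examined by it. Non-smoker 5 had the lowest SD over rows (1.40 against 1.68 for the next, a gap of 0.595 of the range) and the lowest mean correlation with other arrays (0.843 against 0.941, a gap of 0.876). It was also the array apart in 9 of the 17 genes. It was highest for S100B (6.07, gap 0.588), FADS2 (5.82, gap 0.5) and TTLL4 (6.41, gap 0.536). It was lowest for MYB (6.63, gap 0.555), AHR (7.54, gap 0.507), SCD (9.02, gap 0.615), PDK4 (7.24, gap 0.523), PPARG (8.82, gap 0.595) and FABP4 (10.01, gap 0.72).

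Non-smoker 1 was highest for the airway secretory genes BPIFA1 (7.17, gap 0.721) and SCGB3A1 (7.07, gap 0.549) and lowest for CXCL11 (3.54, gap 0.482). Non-smoker 3 was lowest for ITIH5 (6.12, gap 0.611) and CST6 (4.82, gap 0.501). Non-smoker 9 was highest for CYP1A1 (5.70, gap 0.51) and lowest for SORL1 (5.55, gap 0.549). Non-smoker 10 was highest for RARA (7.17, gap 0.614).

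Provided that the arrays come from different people, the 190 calls between smokers and non-smokers cannot be put down to how chance grouped the arrays. The splits moved arrays singly, so they cannot decide this if the leading number marks 1 person measured in both batches. Of 100 splits drawn within batches, the real one included, 1 gave as many, and the highest of the others gave 0; for 1.5-fold calls 1 of 100 did, with 103 real and 0 in the others. A drift along the leading number of the labels, which runs with the group, was tested inside the groups. The slope within group and batch made up a median share of -0.0961 of the difference over the 190 rows, where orders shuffled within groups gave -0.315 to 0.308. A drift of constant slope as the whole source would need a share near 1, and the share plus the upper shuffled bound was 0.212. A step between the last smoker array and the first non-smoker array cannot be told apart from smoking.

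The called differences were smaller in batch 1, with a median of 0.539 against 0.676 in batch 2. Their ratio was 0.797, with a 95% bootstrap interval of 0.593 to 1.01 over 2000 resamples of arrays, so with all arrays the pattern is within its spread. Without the 3 arrays of narrow spread the ratio was 0.962 (0.708 to 1.12); a narrower scale of all other batch 1 arrays would put it near 0.922, the slope of batch 1 on batch 2 row means. By the bounds written before the values were seen, both explanations would have been borne out; those bounds were set aside afterwards, because the interval with all arrays already held 1 and the one without the 3 arrays holds 0.922 and 1 alike, so these explanations cannot be told apart. Letter-E arrays as the whole cause would need a ratio of 1 without them. Without them alone the ratio was 0.732 (0.538 to 0.979), and without both sets it was 0.872 (0.6 to 1.11). By the bound written beforehand, the latter counts against this explanation, since the ratio did not rise from 0.962. The evidence is weak, however, as the interval without both sets holds 1, like that with all arrays. Only the interval without the letter-E arrays alone leaves out 1, and that test was chosen after its value was seen. A biological difference between the samples of both batches stays open, untested.

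The interferon list and the T and NK cell markers were both lower in smokers, so fewer lymphocytes, a source of interferon gamma, were a candidate explanation of the lower interferon genes. Without the 3 arrays of narrow spread, the group difference of the interferon mean was -0.455 (SE 0.102), and it was -0.455 (SE 0.185) with the T and NK mean in the fit. On all 23 arrays it was -0.44 before and -0.434 after. The difference left exceeded by over 1 SE the bound set beforehand, which by that rule counts against this explanation as the whole cause. Over the 23 arrays, residuals of both means after batch and group correlated with Pearson's r = 0.0143 (permutation p = 0.948) and Spearman's rho = -0.0543 (permutation p = 0.806), and r was -0.0656 without the 2 arrays farthest out. This was the 1 relation tested. However, the list means are noisy measures of cell content, and such noise makes the adjustment too small. The test therefore cannot exclude fewer lymphocytes as the explanation, and smoking itself stays open as the biological explanation.

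Other splits of the arrays were counted in the same way for the other results. For the 11 passing lists, 3 of 100 splits gave as many, the real one included, which is under the 0.05 level but rests on few splits. The other splits passed a median of 3 lists, and 1 other split gave 14 lists and another 12, with 0 rows called in either. Chance is thus not firmly excluded for this count. Both those splits put 2 of the 3 arrays of narrow spread among the smokers, as the real grouping does. The split with 14 lists kept 10 of the 13 real smokers. The count of 248 in batch 2 was met by 1 of 100 splits, the highest other giving 2, and the 6340 rows between batches by 1 of 100, the highest other giving 0. Chance cannot be excluded for the 1 call in batch 1, which 6 of 100 splits matched with at most 1 call. For the 0 interaction calls in limma (818 at an unadjusted p under 0.05) the splits decide nothing, since all 100 of 100 must give at least 0.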

How the results depend on the processing

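Leaving out the 3 arrays of narrow spread was chosen after the data were seen. Calls were 189 with batch as a random block or with median centring, 190 with quantile normalization (113 higher, 77 lower), 199 with trend and robust settings, 140 with no batch term, 159 without rows below the median and 217 with a milder filter on dim rows. Larger moves came from array weights (862 calls, 230 of 1.5-fold or more), leaving out the 3 arrays of narrow spread (498 and 177), leaving out the letter-E arrays (69 and 46), batch 1 alone (1 and 1, with 6 lists) and batch 2 alone (248 and 160). Array weights were lowest for the same 3 arrays (0.115 to 0.201). Normal scores of ranks gave 0 calls in limma, with 2072 rows at an unadjusted p under 0.05, all 190 among them. In that fit limma gave every row the same moderated spread, and the smallest adjusted p was 0.0572. With the replicate number as a replicate block, 20 rows were called, all among the 190 and all of 1.5-fold or more, and 12 lists passed. These replicate numbers join a smoker to a non-smoker, and by them the arrays did not pair. After batch and group, correlations of same-numbered arrays ran from -0.192 to 0.0665, and 0 of 10 correlated best with their own number. This cannot show whether people were measured in both batches, since pairs by leading number were not checked. Lists passing numbered 3 with an estimated correlation, 4 with fry, 6 in batch 1 alone and 9 to 12 in all other settings apart from single arrays left out. As limma's camera takes no random block, that fit of the lists was not run. The batch term called 1174 rows after quantile normalization, which acts on the spread that differs between batches. For the other changes the cause was not tested, except that fewer arrays were fitted where some were left out.

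Leaving out each array in turn gave 135 to 307 calls, 79 to 135 of 1.5-fold or more, and 7 to 11 lists; 307 came without smoker 2 and 7 lists without non-smoker 5, and at least 130 of the 190 stayed called. None of the 52 called named genes changed sign and no passing list changed direction in its test in the settings run for them. The medians of 2 passing lists changed sign: that of dendritic cells in 13 settings, 11 of them with 1 array left out (lowest -0.04), and that of matrix proteases in batch 1 alone. Of the named genes that were not called, 5 changed sign. The airway list did not pass in batch 2 alone or with either filter on dim rows, nor the matrix protease list without rows below the median, nor the dendritic list there, with quantile normalization or with array weights, nor the lysosome list with the replicate block. Some lists that did not pass in the main fit passed in an alternative. Cell cycle passed in batch 2 alone, and iron and haem in batch 1 alone. Oxidative phosphorylation passed in batch 1 alone and with the replicate block, and neutrophils with that block and without rows below the median. Immediate early genes passed with array weights, in batch 2 alone, and without smoker 1 or smoker 2. Signal over background was not used here.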

Other observations

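The tests of letter-E arrays against other smokers and against other sets of 3, and those without the 3 arrays of narrow spread, were chosen after the data had been seen.

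The oxidative phosphorylation list did not pass in the main fit (adjusted p = 0.229), with a median of -0.05, and cytochrome c (CYCS) was the 1 called of 34 members, at 1.33-fold lower. The list's median was -0.14 in batch 1, where it passed as lower, and 0.04 in batch 2. Glycolysis and hypoxia genes (adjusted p = 0.395), cell cycle genes (adjusted p = 0.532), immediate early genes (adjusted p = 0.111) and metallothioneins (adjusted p = 0.98) held 0 calls each in limma, with 5, 4, 4 and 0 members at an unadjusted p under 0.05. Only 6 of the 13 genes in the metallothionein list had a row with 1 symbol, so the others were not examined. The kinase PDK4 differed by -0.43 (adjusted p = 0.151), cyclin CCND2 by 0.39 (adjusted p = 0.108), FOS by -0.41 (adjusted p = 0.195) and MT1L by -0.84 (adjusted p = 0.707). Without the 3 arrays of narrow spread limma called PDK4 as lower (adjusted p = 0.0341), PFKP of the same list as higher (adjusted p = 0.0457) and 1 cell cycle gene as higher. Recruited monocyte markers did not pass (adjusted p = 0.229), with PLAC8 at -1.17 (adjusted p = 0.187); adjusted over the list alone 2 fell, and without the 3 arrays of narrow spread 3 did. Without the 3 arrays of narrow spread, 7 members of the NRF2 list rose, 9 of the interferon list fell and 1 rose, and 8 of the T and NK list fell. The matrix protease, complement and airway lists had 3, 3 and 1 called members there, as many as with all arrays.

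Lists of further cell types did not pass either: B and plasma cells (adjusted p = 0.514), alveolar epithelium (adjusted p = 0.98), eosinophils and mast cells (adjusted p = 0.946), erythrocytes and platelets (adjusted p = 0.854) and fibroblasts and endothelium (adjusted p = 0.946). Of the B cell list CD22 differed by 0.41 (adjusted p = 0.0852) and BANK1 by -0.38 (adjusted p = 0.123). Of the alveolar epithelium list SFTPD differed by 0.17 (adjusted p = 0.926) and CLIC5 by -0.33 (adjusted p = 0.739). In the other lists HPGDS differed by -0.38 (adjusted p = 0.679), PPBP by -0.60 (adjusted p = 0.732) and PECAM1 by -0.14 (adjusted p = 0.861). Without the 3 arrays of narrow spread limma called CD22 (adjusted p = 0.0174), BANK1 (adjusted p = 0.0122) and HPGDS (adjusted p = 0.0377), with the same signs.

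The 4 dendritic markers that rose, CD1A, CD1C, CD1E and CD207, stood beside 14 markers that did not pass with all arrays. FCER1A differed by -0.09, FLT3 by -0.06, CCR7 by 0.09 and CLEC10A by 0.31 (adjusted p = 0.414). Without the 3 arrays of narrow spread CLEC10A passed as well, at 0.25 (adjusted p = 0.0492). These members were chosen after their values were seen. CD1B, chosen likewise, differed by 1.22 (adjusted p = 0.0736).

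The 3 smoker arrays with the letter E weighed heavily in the count of calls. Leaving them out left 69 calls. Each of the 50 sets of 3 other smokers with the same batches left more, 81 to 365 (median 190). The other smokers of batch 1 include smokers 2 and 10 of narrow spread, so most of these sets left such an array out. Leaving out smoker 2, an array of narrow spread, by itself gave 307 calls. The median and the highest count may thus overstate the contrast with the letter-E arrays. Sets without arrays of narrow spread were not counted apart. A direct test of letter-E against the other smokers called 0 rows in limma, with 632 at an unadjusted p under 0.05 where chance alone would give 1101. In all 69 rows called without them, the letter-E arrays differed from non-smokers with the same sign. In the direction of the call, the median difference over these rows was 0.936 on the letter-E arrays and 0.9 on the other smokers. CYP1B1, a single gene not called in the direct test, was 3.35 higher than in non-smokers on the letter-E arrays and 2.22 higher on the others.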
